A study of Macaca mulatta with 4 samples.

How the data were processed

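DNase-seq was measured in 4 libraries from rhesus macaque morulae, AG replicates 1 and 2 and GG replicates 1 and 2, grouped by their labels. Per the labels, cells were treated with 40 U/ml DNase I for 5 min at 37 °C. The authors deposited 1 list of hotspots per library, in which each hotspot has a chromosome, a start, an end and a score. Lists are per library and were not pooled, and their names give a false discovery rate of 0.01. The scale of the deposited score and the program that called hotspots are not given in the sources used here, so the score served to rank and filter hotspots within a list. The exception is the choice of named regions, which took the lower of the scores in the 2 libraries of a group. The lowest score in each list was 4.33, 4.13, 4.07 and 4.16 in AG replicates 1 and 2 and GG replicates 1 and 2. Per the submitters' processing notes, the build was rheMac8 and the tools included Trim Galore, Bowtie2, SAMtools and deepTools 3.3.1, with no roles given. Sequencing batch and date are not given in the sources used here. The lists hold no read counts, so depth is unknown, no counting interval can be given, and a longer list can come from deeper sequencing. The 2 lists of a group were clearly different, with Jaccard indices of 0.168 and 0.247, and each counted as 1 library.

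Hotspots were counted and their covered bp summed per library, with exact two-sided permutation tests of group means. Pairs of lists were compared by Jaccard index in bp and by the share of hotspots with at least 1 bp of overlap, beside 20 shifts of positions along chromosomes. Overlapping or touching hotspots of all lists were merged, and a region counted as present in a library with at least 1 bp of overlap. A region was AG-only when present in both AG and neither GG library, and GG-only in the reverse case, set beside the 2 splits that mix AG with GG libraries. Chromosome shares are percentages of a library's covered bp. Hotspots per Mb used the end of the last hotspot on a chromosome in any list as its length. AG-only and GG-only regions per autosome were compared by Fisher's exact test with Benjamini-Hochberg adjustment.

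For windows of 1 Mb with a mean of at least 2000 covered bp, values were log2 of covered bp plus an offset of 1000 bp, divided by the library's mean of this over windows. Fold changes are on that scale, which understates differences of sparse windows. They were tested with limma (lmFit and eBayes, trend and robust off) at a Benjamini-Hochberg adjusted p of 0.05, without the replicate number as a block. The window and region steps were tested on simulated data. Of 2682 simulated windows, limma recovered 21.2% of those changed by log2 1, 67.3% by log2 2 and 88.6% by log2 3. It called 5 of 2482 unchanged windows. Changed windows were drawn at random, with normally distributed noise at each window's own spread, so these shares need not hold for the deposited lists. All planted regions were found, which was certain because they were planted without missed calls. That step checked only the counting of regions. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.

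The tests of number, overlap, group-only regions, chromosome shares and windows, the rule for named regions and the alternatives listed first were chosen before the data were examined. The correlation of differences between separate libraries and most tests of the closing section, which names them, were chosen afterwards. The rule named, per direction, the 5 group-only regions with the highest score in the weaker library and the 5 windows with the smallest p. Alternatives were the higher-scoring 50% of each list, lists shortened to the number of the shortest, leaving out each replicate, autosomes only, 50% of a region covered, merging within 150 bp, windows of 200 kb, an offset of 10000 bp, no minimum, median scaling, counts of hotspots, a variance trend and a replicate block. Lists shortened to equal covered length, hotspots of at least 100 bp, centring within chromosomes, windows from shortened or higher-scoring lists, and chromosome density from single libraries were added after the data were seen. Planned analyses of promoters, imprinted and other gene lists, genomic location and sequence motifs were left out, since no genome or annotation of rheMac8 was used here. RNA-seq, bisulfite sequencing and CUT&RUN data of the study were not analysed here.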

Results

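DNase-seq was carried out on rhesus macaque (Macaca mulatta) embryos at the morula stage, the compact ball of cells that precedes the blastocyst. Androgenetic (AG) embryos carry nuclear genomes from sperm only, and gynogenetic (GG) embryos carry genomes from the oocyte only. A comparison of the 2 kinds of embryo thus sets paternal against maternal chromosomes. Donor animals and the making of the embryos may also differ between the groups and were not separated from parental origin. DNase I cuts open chromatin more readily than closed chromatin, and a hotspot is a stretch of the genome with more cuts than its surroundings. There were 4 libraries, 2 of AG and 2 of GG embryos, each with its own list of hotspots at a false discovery rate of 0.01. The lists hold positions and a score for each hotspot but no read counts, so the sequencing depth of each library is unknown. The labels do not say that replicates came from separate embryos or separate cultures. P-values that compare libraries thus measure only the spread between these samples, which may be technical. P-values across regions, neighbouring windows or chromosomes do not measure that spread. The score is the authors' own value and was used to rank and filter hotspots within a list, apart from the choice of named regions, which used the lower score of the 2 libraries of a group. Positions refer to the rheMac8 build, counted from 1, and were not annotated with genes because no annotation of that build was used here.

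The first question was how much open chromatin each kind of embryo yielded. AG replicate 1 had 64730 hotspots covering 67.8 Mb and AG replicate 2 had 85318 covering 84.3 Mb. GG replicate 1 had 93171 hotspots covering 102 Mb and GG replicate 2 had 84865 covering 93.2 Mb. Both GG libraries therefore covered more of the genome than either AG library, with means of 97.6 ± 6.33 Mb and 76.1 ± 11.7 Mb (SD, n = 2 libraries each). Numbers of hotspots overlapped between the groups, at 75024 ± 14558 in AG and 89018 ± 5873 in GG. Two-sided exact permutation tests gave p = 0.333 for covered length and p = 0.667 for number, and 0.333 is the smallest p that 2 libraries against 2 can give. The AG minus GG difference depended on AG replicate 1: without it, covered length differed by -13.3 Mb against -21.6 Mb with all libraries, and number by -3700 against -13994 (-24288 without AG replicate 2). With every list shortened to the number of the shortest, covered length differed by -12.1 Mb.

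The next question was whether hotspots of one kind of embryo were more alike than hotspots of different kinds. The GG libraries shared the most, with a Jaccard index (shared over total covered bp) of 0.247. The AG libraries had an index of 0.168, inside the range of 0.143 to 0.173 of the 4 pairs of an AG with a GG library. Within AG, 34.5% of the hotspots of the shorter list overlapped one of the other list, within GG 42.0%, and between groups 26.5 to 37.9%. After lists were shifted along the chromosomes, at most 7.83% did so in any pair (20 shifts per pair). In the higher-scoring 50% of each list the AG pair reached 0.210, slightly above the 4 mixed pairs (0.173 to 0.206), so whether AG libraries were more alike by single positions depended on the lists used. There are only 3 ways to split 4 libraries into pairs, so no exact p under 0.333 was possible, and the mean excess within groups, 0.0498 in Jaccard index, came to 0.0101 without GG replicate 1, to 0.0105 without GG replicate 2, to 0.104 without AG replicate 1 and to 0.0750 without AG replicate 2.

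Hotspots with high scores were found again far more often than those with low scores. In AG replicate 1, 12.7% of the lowest score decile and 81.5% of the top decile overlapped a hotspot of AG replicate 2. The corresponding shares were 9.24% and 74.5% for AG replicate 2, 14.0% and 87.9% for GG replicate 1, and 18.1% and 89.4% for GG replicate 2.

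**Figure D1:**
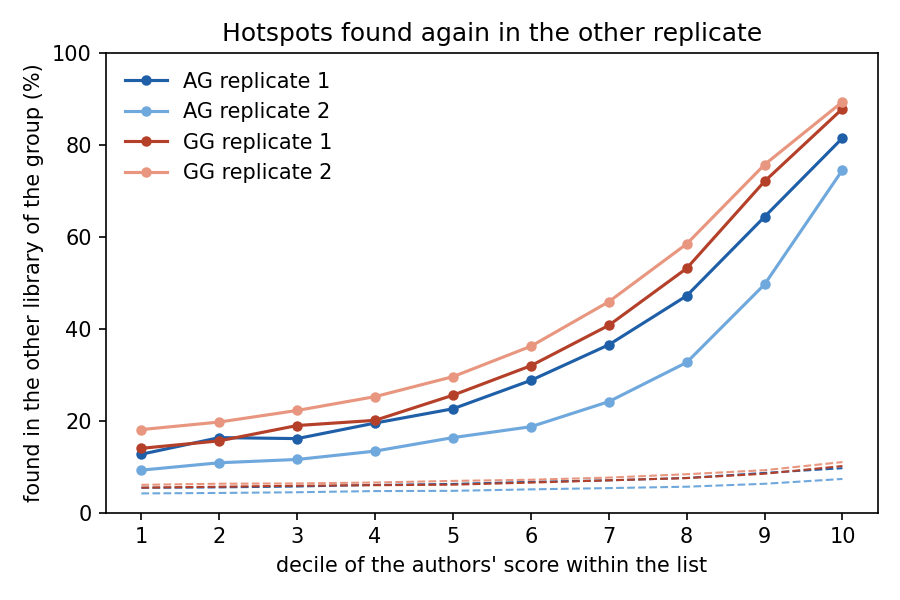
Share of hotspots (%) that overlapped a hotspot of the other library of the same group, by decile of the authors' score within each list, for the 4 libraries (solid lines), with the share after position shifts (dashed lines). The share in the top decile lay between 74.5% and 89.4%, against 9.24% to 18.1% in the lowest.

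Regions open in only one kind of embryo were then sought in the union of the 4 lists, which held 222970 merged regions. Of these, 167077 (74.9%) were called in 1 library, 30685 (13.8%) in 2, 12042 (5.40%) in 3 and 13166 (5.90%) in all 4. Regions found in both AG and neither GG library numbered 4730, and those in both GG and neither AG library 12226, 2.58 times as many. Pairs made of an AG and a GG library shared 2874 to 4051 regions that the remaining libraries lacked. With lists shortened to equal number, AG-only regions numbered 4579, GG-only regions 8559 and those of the mixed pairs 2169 to 3063. With lists shortened to equal covered length, a comparison added after the data were seen, AG-only regions numbered 5076, GG-only regions 5856, and those of the mixed pairs 1748 to 2572. The excess of GG-only over AG-only regions was thus smaller at equal number and small at equal length, while both counts lay above those of every mixed pair in each case. For AG-only regions this does not show that the AG libraries were alike. A region in both GG libraries cannot count for a mixed pair, so strong overlap within GG lowers the mixed counts. By Jaccard index the AG pair (0.168) lay inside the range of the mixed pairs (0.143 to 0.173). Counts of regions carry no test here, and with 1 library of a group left out a region needs only 1 library to count, which gave 55747 and 34981 AG-only regions without AG replicates 1 and 2, and 54040 and 60458 GG-only regions without GG replicates 1 and 2.

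**Figure D2:**
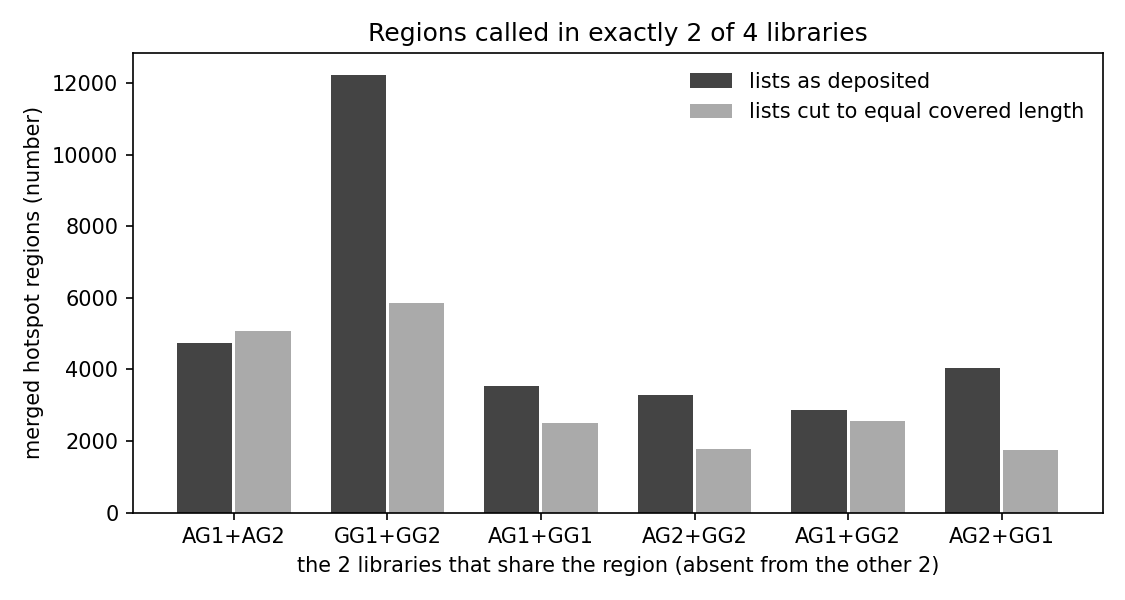
Number of merged regions called in exactly 2 of the 4 libraries, for each pair, in the lists as deposited (dark bars) and in lists shortened to equal covered length (light bars). The GG pair shared 12226 regions as deposited and 5856 at equal length, and the AG pair 4730 and 5076.

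The AG-only region with the highest score in its weaker library lay on chromosome 16 at 49112515 to 49117881, with scores of 596 in AG replicate 1 and 365 in AG replicate 2. It was followed by chromosome Y at 11244082 to 11245442 (scores 242 and 229), the only part of Y in any list. GG embryos have no sperm genome and so no Y, which fixes this region as AG-only whatever its chromatin. The other AG-only regions of this rank were chromosome 2 at 7090144 to 7091611 (95.8 and 139), chromosome 6 at 105126600 to 105127334 (57.1 and 47.0) and chromosome 16 at 24047939 to 24052866 (44.7 and 54.2). Among GG-only regions, chromosome 17 at 2304466 to 2305828 ranked first, with scores of 142 in GG replicate 1 and 98.9 in GG replicate 2. Chromosome 15 at 16560373 to 16561393 (47.9 and 51.7) and chromosome 19 at 41158096 to 41158346 (45.9 and 53.3) followed. The latter had only 44 bp of its 251 bp called in GG replicate 2. Next were chromosome 8 at 7270699 to 7271953 (scores 49.5 and 38.2) and chromosome 17 at 9106018 to 9106934 (39.2 and 36.2). Such scores were rare, since the median score in the weaker library was 4.98 over all AG-only and 5.04 over all GG-only regions.

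Chromosomes were compared next, with the X first because GG embryos have it from the oocyte and AG embryos, where they carry it, from sperm. Chromosome X held 17 and 48 hotspots in the AG libraries and 82 and 117 in the GG libraries, and its share of covered bp was 0.0171 ± 0.00836% in AG and 0.0396 ± 0.0109% in GG (SD, n = 2 each). The share was 2.32 times higher in GG (two-sided exact permutation p = 0.333). The AG minus GG difference was -0.0225 percentage points, -0.0148 without GG replicate 2 and -0.0717 for shares of the number of hotspots. Sperm carry X or Y and both AG lists held a Y hotspot, so AG embryos may lack an X. Both AG lists also held X hotspots, so a lack of X was not shown. X copies were not measured, so the higher share in GG was not separated from X copy number. In every library X was almost empty: autosomes had 212, 98.7, 63.1 and 40.3 times as many hotspots per Mb in AG replicates 1 and 2 and GG replicates 1 and 2. Hotspots on X had median widths of 283 to 469 bp, against 891 to 920 bp on autosomes. Of 193 merged X regions, 148 were called in 1 library and 8 in all 4. Chromosome Y had 1 hotspot in each AG library and none in either GG library, whose embryos have no Y.

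Among autosomes, chromosome 19 took 5.33 ± 0.302% of covered bp in AG and 3.65 ± 0.267% in GG, 1.46 times more in AG (SD, n = 2 libraries each). Chromosome 20 followed with 3.59 ± 0.0680% and 2.50 ± 0.102%, 1.43 times more in AG. Chromosomes 10, 16 and 11 were also higher in both AG than in both GG libraries, by 1.26, 1.19 and 1.05 times. Chromosome 5 had 4.49 ± 1.04% in AG and 5.69 ± 0.295% in GG, 1.27 times more in GG, and chromosome 4 had 5.79 ± 0.807% and 7.17 ± 0.727%. Chromosomes 17, 8, 2 and 3 were higher in both GG than in both AG libraries, by 1.17, 1.12, 1.11 and 1.06 times. Sizes depended on single libraries and on the lists used: the AG minus GG difference of chromosome 5 was -1.20 percentage points with all libraries, -0.465 without AG replicate 1, -1.93 without AG replicate 2 and -0.775 in the higher-scoring 50% of each list. Without AG replicate 1, chromosomes 3, 4 and 8 also came closer to 0 (-0.224, -0.817 and -0.319, from -0.402, -1.39 and -0.556). So did chromosomes 4 and 17 without GG replicate 1 (-0.874 and -0.267, the latter from -0.404) and chromosomes 2 and 16 without GG replicate 2 (-0.420 and 0.441, from -0.698 and 0.809). No left-out library moved chromosomes 10, 11, 19 or 20 by over 1.5 times, though chromosome 11 was at 0.0769 in the higher-scoring 50% of each list and 0.354 by number of hotspots, from 0.234, and chromosome 19 at 1.10 by number of hotspots, from 1.68. Shares of a library add up to its whole, so autosomes are not independent and a count of them carries no test. The groups did not overlap for 11 of 20 autosomes, where chance gives 6.67 (33.3%). Each of these differences had a two-sided exact permutation p of 0.333, and with 3 libraries, where chance gives 13.3, the number was 12 without AG replicate 1, 14 without AG replicate 2 and 18 without either GG library.

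**Figure D3:**
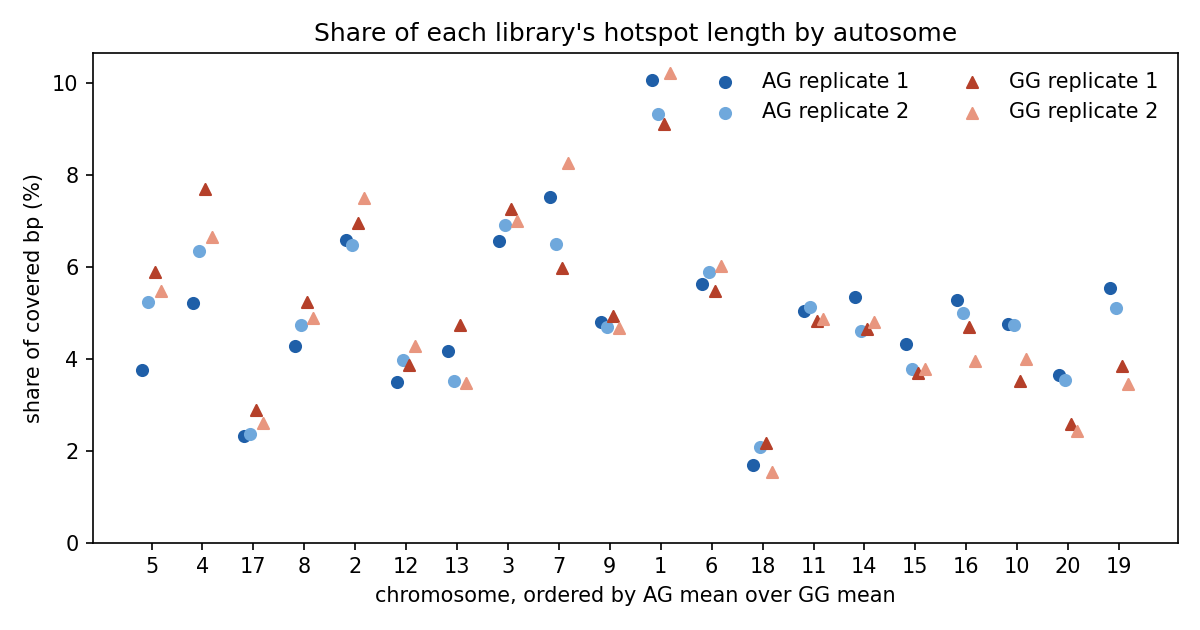
Share of each library's covered bp (%) on each of the 20 autosomes, ordered by the AG mean over the GG mean, for AG (circles) and GG libraries (triangles). Chromosomes 19 and 20 lie at the right, with AG means 1.46 and 1.43 times the GG means, and chromosome 5 at the left.

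Regions found in one group only were also spread unevenly over the autosomes. Chromosome 19 held 6.51% of AG-only and 2.48% of GG-only regions, and 7.63% of the regions called in all 4 libraries. Chromosome 20 held 4.55% of AG-only and 2.26% of GG-only regions, and chromosome 5 held 3.87% and 6.49%. By two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over 20 autosomes, 10 differed at 0.05. Chromosomes 10, 16, 19 and 20 held a larger part of AG-only regions, and chromosomes 2, 4, 5, 8, 9 and 17 of GG-only regions. The adjusted p for chromosome 19 was 9.21e-32 with an odds ratio of 2.74. Regions are not replicates, so these tests compare these lists and not the 2 kinds of embryo.

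Windows of 1 Mb were compared to find which parts of chromosomes differed. The smallest p belonged to chromosome 5 from 28000001 to 29000000, where hotspots covered 2.11 and 2.57 kb in the AG libraries and 48.2 and 36.5 kb in the GG libraries. Scaled to each library, this was a log2 difference of -3.33 (AG minus GG, SE 0.24), or 10.1-fold higher in GG. Chromosome 17 from 67000001 to 68000000 had 0.879 and 1.05 kb in AG against 24.7 and 17.1 kb in GG (log2 -3.10, SE 0.25). In the opposite direction, chromosome 11 from 117000001 to 118000000 had 26.3 and 35.8 kb in AG against 10.6 and 8.35 kb in GG (log2 1.96, SE 0.23). The limma adjusted p was 0.0610 for the window on chromosome 5, 0.0641 for that on chromosome 17 and 0.131 for that on chromosome 11 (n = 2 libraries per group).

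The next windows higher in GG were chromosome 1 from 175000001 to 176000000 (log2 -2.63), chromosome 3 from 140000001 to 141000000 (log2 -1.70) and chromosome 15 from 53000001 to 54000000 (log2 -1.78). The next higher in AG were chromosome 14 from 90000001 to 91000000 (log2 1.64), chromosome 11 from 129000001 to 130000000 (log2 1.48), chromosome 12 from 5000001 to 6000000 (log2 1.65) and chromosome 10 from 75000001 to 76000000 (log2 1.36). By limma, 0 of 2682 windows passed an adjusted p of 0.05, and 483 had an unadjusted p under 0.05, against 38 and 74 in the splits that mix AG with GG libraries. Those mixed splits count low, because a difference between AG and GG adds to the spread within each of their sides. They thus do not measure chance, by which a fraction of 0.05 of the 2682 windows would fall under 0.05. Calls depended on the setting: limma called 218 windows with a variance trend (90 higher in AG, 128 in GG) and 136 with an offset of 10000 bp (37 and 99), and 235 and 252 windows had an unadjusted p under 0.05 without GG replicate 1 or GG replicate 2.

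Differences between AG and GG had the same direction in separate libraries more often than not, a comparison chosen after the data were seen. The difference between AG replicate 1 and GG replicate 1 correlated with that between AG replicate 2 and GG replicate 2 across windows (Pearson r = 0.399, Spearman rho = 0.397), with the same sign in 64.2% of 2682 windows. Windows are not independent replicates. Both AG libraries lay on the same side of both GG libraries in 53.0% of windows (647 higher in AG, 774 in GG), where chance gives 33.3%. The correlation of scaled window values was 0.890 within AG and 0.891 within GG, and 0.775 to 0.813 between groups. Window by window, AG libraries were thus more alike than AG and GG libraries were.

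**Figure D4:**
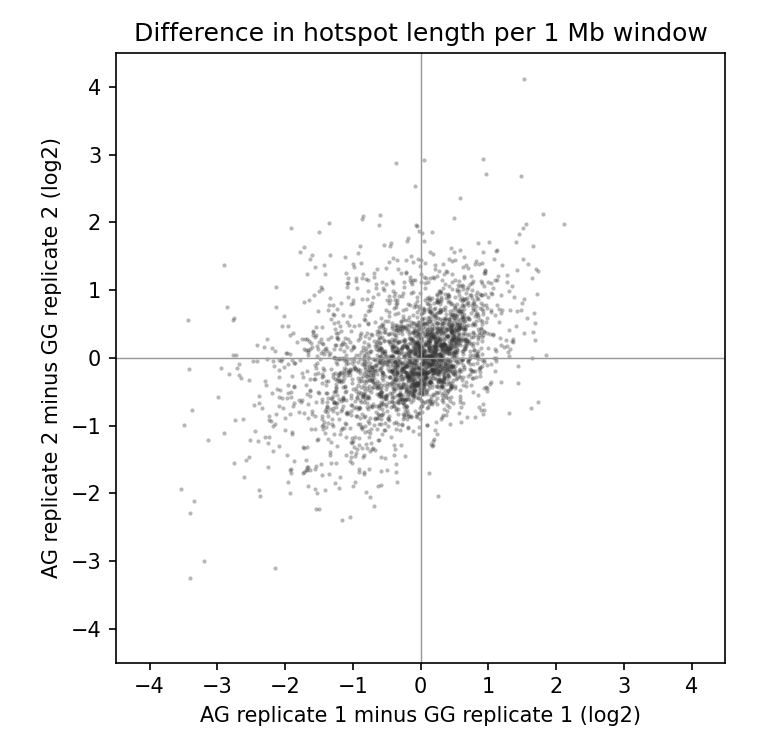
Difference in scaled hotspot length (log2) of each 1 Mb window between AG and GG replicate 1 (x axis) and between AG and GG replicate 2 (y axis), which share no library. Points are 2682 windows, and the correlation was 0.399.

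Many of the widest differences lay on chromosome 5. These windows were chosen by size after their values were seen. Over 4-fold differences occurred in 18 windows, 15 higher in GG and 3 higher in AG, and 8 of the 15 were on chromosome 5. The 18 became 21 and 70 without AG replicates 1 and 2, 28 and 26 without GG replicates 1 and 2, and 0 with an offset of 10000 bp, which shrinks differences of sparse windows. With each library centred within each chromosome there were 9, of which 8 were higher in GG and 4 of these on chromosome 5, and in the higher-scoring 50% of each list 31, of which 22 were higher in GG and 6 of these on chromosome 5. Both were added after the data were seen. Besides the window at 28000001, they included chromosome 5 from 134000001 to 135000000 (log2 -2.84) and from 180000001 to 181000000 (log2 -2.72). The 3 windows higher in AG were chromosome 16 from 35000001 to 36000000 (log2 2.82), chromosome 16 from 37000001 to 38000000 (log2 2.09) and chromosome 11 from 60000001 to 61000000 (log2 2.04). Over 2-fold, 305 windows differed (32 with the larger offset), 234 higher in GG and 71 in AG, of which chromosome 5 had 47 of its 191 windows (24.6%) higher in GG (16 when centred, 37 of 190 in the higher-scoring 50%), while chromosomes 16 and 19 had none. Of all autosomes, chromosome 5 had the fewest regions called in all 4 libraries per Mb (2.66). Next were chromosome 17 (2.70), with 16.7% of its windows over 2-fold higher in GG, and chromosome 18 (2.93), with 7.04%. The sparseness of chromosome 5 was thus not separated from its difference between AG and GG. After scaling, AG replicate 1 lay below AG replicate 2 in 12 of the 15 windows higher in GG, and in 1487 of all 2682 windows.

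**Figure D5:**
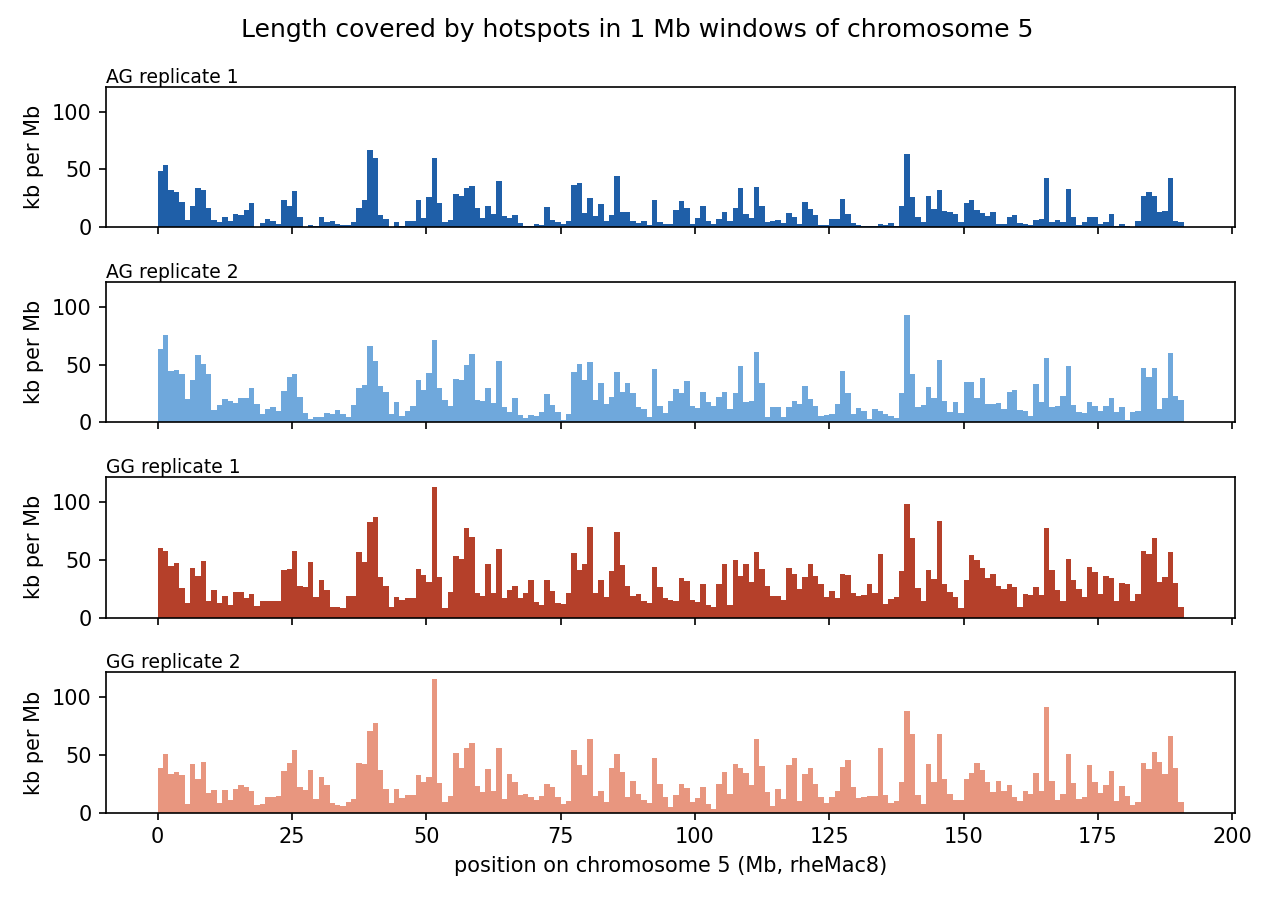
Length covered by hotspots (kb) in each 1 Mb window of chromosome 5 (x axis in Mb, rheMac8) in the 4 libraries. Around 28 Mb both AG libraries were nearly empty, with 2.11 and 2.57 kb, while the GG libraries had 48.2 and 36.5 kb.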

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

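The comparisons on equal covered length, centring within chromosomes, hotspots of at least 100 bp and windows from shortened or higher-scoring lists were chosen after the result was seen. Covered length and X share did not overlap between groups, so leaving out 1 library could not turn their direction, and it did not turn under the other alternatives run. Hotspot number differed in the same direction without any 1 library, but AG replicate 2 had 453 more hotspots than GG replicate 2. With lists shortened to the number of the shortest, the AG minus GG difference in covered length was -12.1 Mb, from -21.6 Mb. With the higher-scoring 50% of each list, AG-only regions numbered 2545 and GG-only regions 6936, and the AG minus GG share of chromosome X was -0.0329 percentage points (-0.0717 by number of hotspots, -0.0225 as reported). With lists shortened to the covered length of the shortest, GG-only regions numbered 5856. When its own group loses 1 library, a region needs only the library that is left. When the other group loses 1, a region need be absent only from the library that is left. Leaving out 1 replicate in turn thus gave 6455 (other group) to 55747 (own group) AG-only and 16111 (other group) to 60458 (own group) GG-only regions. It also gave a mean excess of the Jaccard index within groups of 0.0101 to 0.104, 235 to 612 windows at an unadjusted p under 0.05, and 12 to 18 autosomes whose shares did not overlap. By limma, 0 windows passed as planned, against 136 with an offset of 10000 bp, 2 without a minimum, 2 with median scaling, 16 centred within chromosomes and 218 with a variance trend. Windows of 200 kb gave 0 calls, and by limma 1954 of 13264 had an unadjusted p under 0.05, against 483 of 2682 windows of 1 Mb. Apart from the shorter windows and the left-out libraries, whose construction differs, the cause was not tested. Differences in share were recomputed only for the 11 autosomes that did not overlap. By number of hotspots and in the higher-scoring 50% of each list, 22 of 22 differences kept their direction, and leaving out 1 library could not turn them. Of all 66 values, 13, on 9 chromosomes, changed by over 1.5 times. Replicate numbers shared between groups did not pair the libraries, since differences within AG and within GG correlated at -0.0842. With a replicate block, limma called 0 windows, 464 had an unadjusted p under 0.05, and the paired difference in covered length was -34.3 Mb for number 1 and -8.87 Mb for number 2. Alternatives for promoters, gene lists, genomic location and sequence were not run. Depth is unknown, so a hotspot missing from a list may lie below that library's detection limit.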

Other observations

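Only the tests of score deciles and of spread over windows were fixed before their results were seen. Those on recurring window differences, chromosome X, neighbouring windows and chromosome density, with its repeats on single libraries, and the spread without AG replicates 1 or 2 were chosen after the result was seen. For windows, the first plan was to count called windows, which was void because limma called 0, and the correlation between separate libraries took its place. For neighbouring windows, the condition that the correlation exceed those between libraries of one group was added after the values were seen.

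Across 20 autosomes, the log2 ratio of AG to GG share correlated with the number of regions called in all 4 libraries per Mb (Pearson r = 0.737, permutation p = 0.0002, Spearman rho = 0.701, permutation p = 0.00088). Chromosomes are not replicates of the 2 kinds of embryo, so the permutation p-values here describe these lists only. Without chromosomes 19 and 16, the farthest in density, r was 0.729 (permutation p = 0.0006). With lists shortened to the number of the shortest r was 0.723. Shares are already relative to each library, so this is a weak test of the number of hotspots called. Density and ratio come from the same lists, so density was also taken from 1 library and the ratio from the others: r was 0.589 to 0.729, and without chromosomes 19 and 16 it was 0.530 (AG replicate 1, permutation p = 0.0215), 0.725 (AG replicate 2, p = 0.0009), 0.0685 (GG replicate 1, p = 0.791) and 0.495 (GG replicate 2, p = 0.0358). AG hotspots may thus be weighted to hotspot-dense chromosomes, but 1 of these 4 relations rested on chromosomes 19 and 16, the ratio of AG replicate 1 to AG replicate 2 gave r = 0.371 (0.0449 for the GG libraries), and GC content, digestion and signal to noise were not tested and stay open.

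AG minus GG differences of 1 Mb windows recurred in libraries that share no sample, at r = 0.399 and 0.464 for the 2 ways of pairing them. The lower correlation was 0.414 with lists of equal number, 0.442 with each library centred within each chromosome and 0.361 in the higher-scoring 50% of each list. Each stayed above 50% of its first value. For centring, this argues against the copy number of whole chromosomes as the whole cause. The higher-scoring 50% is a weak test of evenly spread weak calls, because it still held hotspots seldom found again. In score decile 6, 18.7% (AG replicate 2) to 36.2% (GG replicate 2) were found in the other library of the group. Equal number is a weak test of the number of hotspots, since window values were already scaled to each library and covered length stayed unequal. Parental origin of the genome may account for the recurring differences. Batch, depth, digestion, signal to noise, embryo quality, donor animals and gains or losses of parts of chromosomes were not tested and stay open.

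Chromosome X was nearly empty of hotspots in all 4 libraries. The lowest ratio of autosomal to X hotspots per Mb was 40.3, in GG replicate 2. That is far more than fewer copies of X could give in embryos that carry an X, for which a bound of 4 was set. The bound does not hold for AG embryos that lack an X, though both AG lists held X hotspots and a lack of X was not shown. In each list the median X hotspot scored above at least 97.1% of autosomal hotspots, which is consistent with a filter or other handling of X before the lists were made and equally with a true lack of weaker X hotspots. These cannot be told apart, since the lists hold no read counts, and the higher X share in GG rests on 17 to 117 hotspots per library. The higher share was also not separated from X copy number.

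Share found again, less the share after shifts, was at least 6.52 times higher in the top than in the lowest score decile in each library. The densest 10% of windows held 3.06 percentage points more of covered bp in AG than in GG, and 3.73 in the higher-scoring 50% of each list, but 1.21 and 2.09 without AG replicate 1 and 4.91 and 5.36 without AG replicate 2. Differences of neighbouring windows correlated at r = 0.419, above all of 10000 shuffles (highest 0.218, permutation p = 0.0001, the smallest they can give), but the difference between the GG libraries gave 0.403 and that between the AG libraries 0.262, so domains that differ between AG and GG were not separated from domains that differ between libraries.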
